A study of Xenopus tropicalis and Xenopus laevis with 11 samples.

How the data were processed

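Germ cell RNA of Xenopus tropicalis and Xenopus laevis was sequenced in 11 libraries. Per the labels' protocols, cells for CLIP were irradiated with UV light, RNA for RIP, small RNAs and the X. laevis RNA-seq came from stage 1-3 oocytes freed of follicle cells by collagenase, RNA was extracted with Trizol and the antibodies were custom made. CLIP tags and 1 set of mRNA libraries were made by a custom small RNA protocol and the other mRNA libraries with a ScriptSeq kit. The labels describe the 3 RNA-seq libraries as poly(A) RNA, and they name no aligner, genome build or filter. The authors deposited the X. tropicalis libraries as counts of reads per distinct sequence, not normalised. The X. laevis files as deposited by the authors hold another kind of value, a 1 for each distinct sequence, so they record presence and not the number of reads. Their names state that rRNA was removed from the RIP and RNA-seq files. CLIP tags were 18 to 34 nt long, X. tropicalis RNA-seq reads 51 nt, small RNAs 11 to 42 nt and X. laevis RIP and RNA-seq sequences 32 nt.

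No genome or transcript sequences were used, because the sources used here hold gene names alone. The matching to reference transcripts that had been planned was replaced by fragments assembled from the reads. For X. tropicalis, RNA-seq reads from base 6 on were joined through k-mers of 21 nt seen at least 2 times into fragments of at least 60 nt, and CLIP tags through k-mers of 17 nt seen at least 20 times for abundant RNAs. X. laevis RIP and RNA-seq sequences were joined through k-mers of 21 nt seen at least 2 times into fragments of at least 80 nt, and small RNAs through k-mers of 21 nt seen at least 4 times into fragments of at least 60 nt. This gave 135374 fragments for X. tropicalis (N50 92 nt), 105372 for X. laevis (N50 195 nt) and 47213 from small RNAs (N50 100 nt). Fragments were named with BLAST 2.17.0 (E value at most 1e-5) by 99 vertebrate protein sequences, 3 of them transposon proteins, which were written down from general knowledge and not taken from a database. A match needed at least 20 residues at 70% identity, or 40 residues at 40% for transposon proteins. Fragments matching the same protein formed a family, so paralogs and homeologs are counted together. X. tropicalis fragments matched 90 families, with a median of 99.7% of the protein covered and a median best identity of 96.1%. X. laevis fragments matched 89, with 100% and 96.0%. Small-RNA-built fragments matched 3, with 95.4% and 61.1%. Ribosomal, small nuclear, transfer and mitochondrial ribosomal RNAs were found through 51 short sequences written down in the same way and extended by similarity (at least 90% identity over 80% of the fragment, E value at most 1e-10).

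Reads were placed on fragments with up to 1 mismatch (exact seed of 18 nt, the first 34 nt from base 6 for 51-nt reads), and reads matching several features were left out. X. tropicalis counts are reads on the sense strand. X. laevis counts are distinct sequences on both strands. Any feature took 41.1%, 53.8%, 62.3% and 50.8% of the reads of ovary Xili CLIP, ovary Xiwi CLIP A, B and testis CLIP, 89.5% and 83.0% of those of stage 3-4 and 5-6 RNA-seq, and 43.5%, 53.6% and 60.4% of the sequences of the Xiwi RIP, Xili RIP and X. laevis RNA-seq. Fragments built from RNA took 2.22% and 1.59% of the small RNAs of the Xiwi and Xili IPs. Distinct sequences saturate with depth, and the families filled a median of 21.4%, 26.1% and 31.5% of their possible positions in the Xiwi RIP, Xili RIP and RNA-seq, with 0 families over 80%, so ratios of abundant families are drawn toward 0. Ribosomal, small nuclear, transfer and mitochondrial ribosomal RNAs and unnamed high-copy CLIP fragments (mean of at least 1000 reads) were left out of the tests.

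Features were families and unnamed fragments. CLIP comparisons used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM scaling, its expression filter, both-sided p and Benjamini-Hochberg adjustment at 0.05. The fits have 1 residual degree of freedom among the CLIP libraries, from Xiwi CLIP A and B, and the lone libraries are assumed to vary like that pair. For comparisons with poly(A) RNA, the mean of the stages was the reference. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and at the estimated correlation. Comparisons of 1 library with 1 used log2 ratios of scaled counts with a pseudocount of 1 on that scale. Counts were scaled to the total placed on families and unnamed fragments, and not to all reads or sequences of the library. Features needed at least 100 counts summed, and the threshold was 2-fold with an interval that excludes 0. The 95% intervals of these ratios come from exact Clopper-Pearson limits on counts without the pseudocount, so a ratio may lie at the edge of its interval. A list was ranked among 10000 random lists of families and fragments of like abundance. Small RNA properties were taken over distinct sequences of 24 to 32 nt. Other work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and assembly and placement in C++ compiled with g++ 11.4.0. DESeq2 1.42.0 was an alternative.

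Of 17 gene lists with 385 genes, 11 had a member among the proteins written down. The blood list (hemoglobins) was not measured in any comparison. The lists for egg coat, sperm and meiosis, liver and egg yolk, proteasome, domesticated transposon genes and transposon-related annotation had no member, so they gave no result. The families named in the text were those 10 per direction with the largest change among features past the threshold with all libraries on the same side and at least 20 counts per library in the higher group. Where fewer than 5 passed, the 10 largest with at least 50 counts summed were named and said not to have passed, and in comparisons of 1 library with 1 the 10 largest ratios with at least 100 counts summed. Members of the piRNA pathway and germ plasm lists were named besides. Transposon proteins took no place among these. Some families that the rule names are not reported here.

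Comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The assembly, the last set of proteins, the 25% coverage a family needed and the handling of high-copy CLIP fragments were set after first looks at how many fragments were named, before any comparison was computed. The 2-fold threshold, the counting of distinct sequences on both strands in X. laevis and the use of both strands for small RNA density were set after the structure of the files was known. Counting the sense strand alone in X. laevis was chosen after the data were seen. Transcript regions of CLIP tags were not analysed here, since no coding annotation was used.

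The tests were checked on simulated counts with 100 features changed at each of 4-fold and 16-fold. Recovered changes were 1% and 23% for testis against ovary Xiwi CLIP, 9% and 52% for Xili against Xiwi CLIP, 39% and 99% for Xiwi CLIP against poly(A) RNA and 9% and 76% for Xili CLIP against poly(A) RNA. False calls were 1 of 2135, 8 of 2157, 3 of 6651 and 6 of 5463 unchanged features. All simulated libraries were drawn with the dispersion of the fit, so lone libraries varied like Xiwi CLIP A and B by design. The false calls therefore cannot show how the tests behave where lone libraries or assays vary otherwise. Changed features were drawn from the more abundant features alone. For the ratio of stage 5-6 over stage 3-4 RNA-seq, 95.8% of intervals covered the simulated value, with a median error of 0.11. Ratios of distinct sequences were not simulated in this way.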

Results

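The series covers 11 sequencing libraries made to find the RNAs held by the Piwi proteins Xiwi and Xili in germ cells of the frogs Xenopus tropicalis (6 libraries) and Xenopus laevis (5 libraries). CLIP recovers RNA crosslinked to a protein by UV light before immunoprecipitation, and RIP recovers RNA that comes down with the protein. From X. tropicalis there were 2 ovary Xiwi CLIP replicates (A and B), 1 ovary Xili CLIP library, 1 testis Xiwi CLIP library and 1 poly(A) RNA-seq library each from ovary oocytes of stages 3-4 and 5-6. From X. laevis oocytes of stages 1-3 there was 1 library each of small RNA from a Xiwi and from a Xili immunoprecipitation (IP), of Xiwi RIP, of Xili RIP and of RNA-seq. Total read counts were 613343 for ovary Xili CLIP, 2086418 and 1263170 for ovary Xiwi CLIP A and B, 1552150 for testis Xiwi CLIP, 73311676 for stage 3-4 RNA-seq and 58667148 for stage 5-6 RNA-seq. The X. laevis files list each distinct sequence once, so their depth in reads is unknown. They held 20113225 distinct sequences for the Xiwi IP, 23841486 for the Xili IP, 8610325 for the Xiwi RIP, 8131782 for the Xili RIP and 8256085 for the RNA-seq. Families are named by the protein that the translation of an assembled fragment matched, and no chromosome position is known for any of them. Only the ovary Xiwi CLIP has replicates, and confidence intervals (95%, exact binomial) cover counting error only.

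Ribosomal RNA was the largest identified part of the CLIP libraries. Cytosolic rRNA took 20.5% of reads in ovary Xili CLIP, 36% and 46.6% in ovary Xiwi CLIP A and B, and 41.4% in testis Xiwi CLIP, against 1.48% and 4.12% in the RNA-seq of stages 3-4 and 5-6. Counting each distinct sequence once, the rRNA shares were 4.07%, 4.62%, 7.16% and 5.38% in the CLIP libraries. Named protein families took 1.22%, 0.929%, 0.776% and 0.287% of reads in the same order of CLIP libraries, and unnamed fragments took 15.6%, 11.2%, 10.2% and 4.18%. Reads on 18S rRNA were 87.1% sense in ovary Xili CLIP, 95% and 93.2% in ovary Xiwi CLIP A and B, and 99.6% in testis. U2 snRNA behaved differently: 58.1% (55.8 to 60.4) and 57.1% (54.9 to 59.3) of its reads were sense in ovary Xiwi CLIP A and B, against 92.8% in ovary Xili CLIP and 99.1% in testis Xiwi CLIP. Reads on transposon proteins came from the Tc1/mariner transposase alone, the only transposon protein matched by X. tropicalis fragments. They were mostly antisense in CLIP, with a sense share of 28.2% of 39 reads in ovary Xili CLIP. The share was 15.1% of 185 and 23.6% of 140 in ovary Xiwi CLIP A and B, and 32.7% of 214 in testis. In the RNA-seq it was 90.5% of 7081 and 90.6% of 10514. The 100 most abundant sequences held 35.4% of the testis CLIP reads, against 11.3%, 18.3% and 24.9% in ovary Xili CLIP and Xiwi CLIP A and B. Across 2325 fragments, which are not independent replicates, the log2 normalised counts of Xiwi CLIP A and B had a Pearson correlation of 0.442 and a Spearman correlation of 0.414, with a chi-square of 15.0 per degree of freedom.

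Ovary Xiwi CLIP against ovary poly(A) RNA asks which transcripts Xiwi contacts more or less than their abundance predicts. CLIP and RNA-seq also differ in read length and in how the libraries were made. CLIP tags of 18 to 34 nt span the lengths of the small RNAs (24 to 32 nt). In no CLIP comparison here were small RNAs held by the protein set apart from pieces of contacted transcripts. The tested features were themselves assembled from the RNA-seq reads. A difference between the assays therefore cannot be told apart from a difference in contact. The p-values rest on the spread between CLIP A and B and do not cover a difference between assays. Histone transcripts stood out: the families matching H2B, H4, H3 and H2A all rose in Xiwi CLIP, and so did those of initiation factor EIF5A, cofilin and calmodulin. Transcripts of cytosolic ribosomal proteins fell, with 20 of 27 families past the threshold, as did nucleoplasmin, NME, ferritin and ubiquitin. The log2 fold change was 6.28 ± 0.40 (SE; 2 CLIP libraries against the mean of both stages; edgeR adjusted p 7.63e-51) for H2B, 4.58 ± 0.39 (adjusted p 1.37e-29) for H4 and 2.36 ± 0.55 (adjusted p 7.40e-05) for EIF5A. It was 1.95 for H3, 1.70 for H2A, 1.62 for cofilin and 1.37 for calmodulin, the last turning to -0.17 with no low-count filter. Of the lower families, RPL23 stood at -5.59 ± 0.44 (adjusted p 3.43e-33), RPLP1 at -5.01, nucleoplasmin at -4.25 and NME at -4.19. Ferritin followed at -3.99, ubiquitin at -3.92, RPS23 at -3.89, RPS18 at -3.85, RPS3 at -3.70 and RPL38 at -3.29. Of 9835 features tested, 2149 rose and 3092 fell, and of 86 families 9 rose and 45 fell. The other 2 families that rose, named after their values were seen because their counts were below the naming rule, matched beta-catenin (3.22) and VCP (2.17), and both lost their call with no low-count filter and with the DESeq2 test. The median of all features lay at -0.74 under TMM scaling and at -0.81 under DESeq2 size factors in edgeR, at -0.40 with the DESeq2 test and at -1.59 and -0.96 without replicate A and B. Changes are relative to the scaling used. Of all calls 41.0% were higher, against 71% with the DESeq2 test (653 higher, 267 lower). The histone list had 4 of 4 members up both over all features and adjusted over the list alone, with a median of 3.26 and a camera p of 0.00336 (0.206 with the correlation estimated from the data). The ribosomal protein list had 20 of 27 members down in both counts, with a median of -2.43 and a camera p of 0.000165 (0.514 with the estimated correlation). Neither list changed its direction under the other scaling. With the DESeq2 test 2 histone and 2 ribosomal protein families passed, and with each distinct sequence counted once 4 and 6 did (ribosomal median -0.94). Replication-dependent histone transcripts lack a poly(A) tail in most cells, and poly(A) RNA was the reference here. Of the 3 mitochondrial families COX1 (-2.88) and cytochrome b (-2.81) fell, and COX3 (1.04) did not pass. COX1 stood higher in CLIP A than at stage 3-4, so its fall rests on the stage 5-6 library. Germ plasm and maternal transcripts fell for 4 of 6 families (median -1.44, camera p 0.0401, estimated correlation 0.420), among them DAZL at -1.66, and the Vasa homologue DDX4 did not change detectably (0.78 ± 0.62, adjusted p 0.299, edgeR). Cell cycle families fell in 3 of 4 cases (median -1.92) and both respiratory chain families fell (median -2.68). Of 4 translation factors 1 rose and 2 fell (median -0.64), and hnRNP A (0.41) did not pass.

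**Figure D1:**
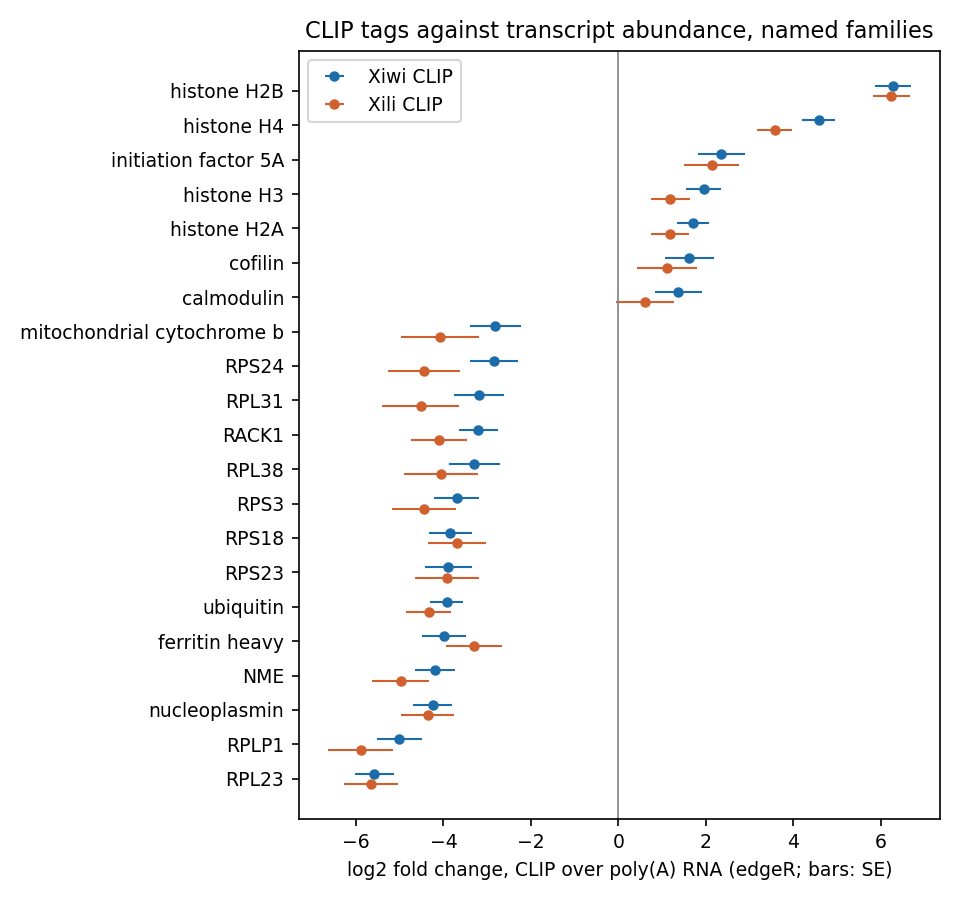
Log2 fold change of CLIP tags over ovary poly(A) RNA for each named family (points: edgeR estimate, bars: SE; blue: Xiwi CLIP, orange: Xili CLIP). Histone H2B sits at 6.28 and 6.24, and RPL23 at -5.59 and -5.66; with no low-count filter calmodulin turned to -0.17 for Xiwi, and H3 and H2A turned to -0.61 and -0.62 for Xili.

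The same question for Xili gave a similar set of families. Histone H2B, H4, H3 and H2A and EIF5A rose in Xili CLIP over poly(A) RNA, and ribosomal protein families, NME, nucleoplasmin, ubiquitin, RACK1 and mitochondrial cytochrome b fell. The log2 fold change was 6.24 ± 0.42 (edgeR adjusted p 1.76e-45) for H2B, 3.57 ± 0.40 for H4, 2.13 ± 0.62 for EIF5A, 1.19 ± 0.45 for H3 and 1.18 ± 0.43 for H2A. With no low-count filter H3 (-0.61) and H2A (-0.62) turned negative. RPLP1 stood at -5.89 ± 0.75, RPL23 at -5.66, NME at -4.97, RPL31 at -4.52 and RPS24 at -4.45. RPS3 was at -4.44, nucleoplasmin at -4.36, ubiquitin at -4.34, RACK1 at -4.10 and cytochrome b at -4.07. Cytochrome b rested on 4 Xili reads, RPL31 on 6, RPS24 on 9 and RPLP1 on 10. Cytochrome b also lay far apart in the stages that form the reference (log2 ratio 4.04, stage 5-6 over stage 3-4). In all, 1466 features rose and 2306 fell, with 6 families up and 40 down. The sixth family up, named after its values were seen, matched beta-catenin (2.48, from 8 Xili reads), and it lost its call with DESeq2 size factors, perfect matches, no low-count filter, both stages as 1 group, the DESeq2 test and distinct sequences. The median of all features was -1.68 under TMM and -1.87 under DESeq2 size factors. Of all calls 38.9% were higher, against 95.9% with the DESeq2 test (139 higher, 6 lower). All 4 histone families rose (median 2.38, camera p 0.000815, estimated correlation 0.182), and adjusted over the list alone the count was also 4. With DESeq2 size factors the 4 histone families stayed above 0, and 2 of them passed. With the DESeq2 test and with each distinct sequence counted once, 0 of the 15 named families kept their call, and 0 histone and 0 ribosomal protein families passed, while the histone median stayed at 2.19 and 2.47 and the ribosomal protein median was -3.05 and -1.30. For ribosomal proteins 19 of 27 fell (20 adjusted over the list alone), with a median of -2.86 and a camera p of 2.98e-05 (0.481 with the estimated correlation), below 0 under the other scaling as well. Germ plasm and maternal families fell in 4 of 6 cases (median -1.83, camera p 0.0110, estimated correlation 0.356). Cell cycle families fell in 3 of 4 cases (median -2.11), both respiratory chain families fell (median -2.81), 1 of 4 translation factors rose and 2 fell (median -0.59), and mitochondrial families fell in 2 of 3 cases (median -2.80). DDX4 (0.33) and hnRNP A (-0.02) did not pass. Xili CLIP is 1 library, so its spread was taken from the Xiwi replicates. Both comparisons with poly(A) RNA share the same RNA-seq libraries and are not independent. The limits stated for Xiwi hold for Xili as well: assay differences cannot be told apart from contact, and small RNAs were not set apart among the tags.

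Comparing ovary Xili CLIP with ovary Xiwi CLIP asks whether the Piwi proteins contact different transcripts. No protein family differed: edgeR called 0 of 86, with 0 higher and 1 lower at an unadjusted p under 0.05, and DESeq2 also called 0. Among the largest differences, none of which passed, ferritin was at 0.77 ± 0.63, SKP1 at 0.72, protein phosphatase 2A at 0.69 and cyclin B at 0.63 in the direction of Xili. The next were thymosin beta at 0.47, ARF1 at 0.47, LDHB at 0.43, HSP90 at 0.36, 14-3-3 zeta at 0.35 and stathmin at 0.33. Without Xiwi replicate B, ARF1 (-0.014) and stathmin (-0.22) changed sign. Toward Xiwi lay RPS24 at -1.52 ± 0.71, RPL31 at -1.25, RPS13 at -1.24, RPL11 at -1.21 and RPSA at -1.20. RPLP0 was at -1.05, histone H4 at -0.94, RPL37A at -0.92, PCNA at -0.88 and RACK1 at -0.81. As a list, the 27 ribosomal protein families had a median of -0.31 and a camera p of 0.0122, which did not hold with the estimated correlation (0.581). This list rested on the replicate used: without Xiwi replicate B all 27 families lay below 0 (median -0.85), and without replicate A 16 did (median -0.13). None of the other lists had a member past the threshold, with medians of -0.19 for germ plasm and maternal, 0.21 for cell cycle, 0.01 for translation factors, -0.58 for histones, -0.25 for mitochondrial and -0.06 for respiratory chain families. The mitochondrial median was 0.18 without Xiwi replicate A, -0.62 without replicate B and 0.21 with distinct sequences. DDX4 was at -0.38 and hnRNP A at -0.37. Over all 2906 features 17 were higher and 2 lower in Xili (unadjusted 122 and 132), and DESeq2 gave 2 and 0. None of the features past the threshold belonged to a named family. On simulated data this comparison recovered 9% of 4-fold changes and 52% of 16-fold changes, so most 4-fold changes would not be detected with these libraries.

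Testis Xiwi CLIP against ovary Xiwi CLIP asks which transcripts Xiwi contacts in the male and the female germ line. There is no testis RNA-seq library, so a difference in contact cannot be told apart from a difference in transcript abundance. Nucleoplasmin, a chromatin protein stored in eggs, fell most among the named families, and calmodulin, the dynein light chain DYNLL1 and TFIIIA, a 5S RNA transcription factor, fell as well. Mitochondrial cytochrome b and COX3 rose, together with the poly(A)-binding protein PABPC1. Nucleoplasmin had a log2 fold change of -5.39 ± 0.98 (SE; 1 library against 2; edgeR adjusted p 0.000895), calmodulin -3.56 ± 0.81, DYNLL1 -3.33 ± 0.84 and TFIIIA -3.16 ± 0.80 (adjusted p 0.00724). Ribonucleotide reductase M2 was at -2.80, cytochrome c at -2.70, NME at -2.53, thymosin beta at -2.52, RPL30 at -2.15 and enolase at -2.01. On the higher side cytochrome b was at 2.61 ± 0.63 (edgeR adjusted p 0.00546), COX3 at 2.27 ± 0.68 (adjusted p 0.0170) and PABPC1 at 1.59 ± 0.60 (adjusted p 0.0457). The Tc1/mariner transposase family, named after its values were seen, also rose (1.72 ± 0.64, edgeR adjusted p 0.0426). GAPDH (2.11), mitochondrial COX1 (1.73), ubiquitin (1.35), RPS12 (1.22), RPS29 (1.17), RPL38 (0.97) and RPL37A (0.83) were the next largest and did not pass. Of 86 families 4 rose and 11 fell, and of 2906 features 250 rose and 780 fell. The tested features were assembled from ovary RNA-seq, so transcripts found only in testis have none. This can lean the counts and the median toward lower. The median of all features lay at -1.37 under TMM and at -1.17 under DESeq2 size factors, and changes are relative to the scaling used. The share of higher calls was 24.3% and reached 94.7% with the DESeq2 test (18 higher, 1 lower) and 81.1% with each distinct sequence counted once (60 higher, 14 lower). All 10 lower families kept their direction under each alternative run, and 6 kept their call with DESeq2 size factors, 1 with distinct sequences and 0 with the DESeq2 test. On the higher side, cytochrome b and COX3 kept their call with DESeq2 size factors, distinct sequences and perfect matches and lost it with no low-count filter and with the DESeq2 test. PABPC1 and Tc1/mariner lost their call under each of these 5 alternatives. For the 3 mitochondrial families, 2 rose (3 adjusted over the list alone), with a camera p of 0.0181 (0.399 with the estimated correlation). None of the 4 histone families passed in edgeR (0 also at an unadjusted p under 0.05 and in DESeq2; median -1.79, camera p 0.577). The ribosomal protein families had a median of 0.11, which turned to -0.24 with no low-count filter and moved to 0.79 and 0.02 without ovary replicate A and B and to 0.95 with distinct sequences, and 1 of 27 fell (0 adjusted over the list alone). Germ plasm and maternal families fell in 2 of 6 cases (3 adjusted over the list alone, median -1.24, camera p 0.464, estimated correlation 0.726), cell cycle in 1 of 4 (2 over the list alone, median -1.48) and respiratory chain in 1 of 2 (median -1.70). Of 4 translation factors 1 rose (median -0.64), and DDX4 (0.01) and hnRNP A (0.14) did not pass. On simulated data this comparison recovered 1% of 4-fold and 23% of 16-fold changes.

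The poly(A) transcriptomes of late (stage 5-6) and mid (stage 3-4) oocytes were compared as 1 library against 1, so there is no replicate check and no p. Mitochondrial transcripts and ribonucleotide reductase M2 had the largest ratios among the named families. RPLP1, RPS27, RPL37A, RPL38, RPS20 and histone H2B were also at least 2-fold higher in late oocytes, while VCP, hnRNP A and nucleoplasmin were at least 2-fold lower. Cytosolic rRNA took 1.48% of reads at stage 3-4 and 4.12% at stage 5-6. The log2 ratio was 5.16 for mitochondrial COX1, 4.98 for COX3, 4.37 for ribonucleotide reductase M2 and 4.04 for cytochrome b. RPLP1 and RPS27 stood at 1.31 each, H2B at 1.24, RPL37A at 1.23, RPL38 at 1.09 and RPS20 at 1.05. On the lower side were VCP at -2.36, hnRNP A at -1.66 and nucleoplasmin at -1.65. Enolase was at -1.51, RAB1 at -1.49, RAN at -1.31, HSP90 at -1.30, and PABPC1 and ARF1 at -1.25 each. Of 56768 fragments 10733 were at least 2-fold higher and 13348 at least 2-fold lower (median -0.23), and of 89 families 11 and 17. The fragment counts were 4217 and 4261 with a pseudocount of 5, and 2049 and 3141 with each distinct sequence counted once. Ratios were scaled to placed reads, 37772037 of 58667148 at stage 5-6 and 56751846 of 73311676 at stage 3-4. Scaled to all reads, each ratio would be lower, and the counts past 2-fold were not computed on that scale. Counting each distinct sequence once, each family named here kept its sign and moved toward 0, and 7 and 5 families passed. Of 27 ribosomal protein families 5 were at least 2-fold higher and 1 at least 2-fold lower. The mitochondrial list ranked above all 10000 random lists of like abundance, the ribosomal protein list (median 0.51) above 97.9% of them and the histone list (median 0.81) above 89.1%. The piRNA pathway families DDX4 and PIWIL1 had a median of -0.98 (above 16.7% of random lists), germ plasm and maternal families -0.59 (22.3%), cell cycle families -0.10 (50.4%), translation factors -0.56 (25.1%) and respiratory chain families -0.66 (23.5%). Vimentin, the 1 measured family of the follicle and somatic gonad list, was at -0.13.

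In X. laevis oocytes, the Xiwi RIP against the oocyte RNA-seq asks which transcripts come down with Xiwi beyond their abundance. Histone H4, H2B and H2A and mitochondrial COX1 were at least 2-fold higher in the RIP. Histone H3, the ubiquitin-conjugating enzyme UBE2D and beta-catenin came next and did not reach 2-fold. TMM scaling lifted H3 past 2-fold and UBE2D just to it. Ribosomal proteins were near the median of all fragments, and the localized maternal transcript Vg1 was the lowest family, with no family at least 2-fold lower. The log2 ratios of distinct sequences were 2.33 (2.18 to 2.50) for H4, 2.27 for COX1, 1.75 for H2B, 1.65 for H2A and 0.95 for H3. UBE2D was at 0.89, beta-catenin at 0.73, EIF4A at 0.33 and PIWIL1, the Xiwi protein's own family, at 0.20 (-0.13 to 0.54). The lowest were Vg1 at -0.69 (-0.85 to -0.53), VCP at -0.57, RPLP0 at -0.52 and RPL23 and HSC70 at -0.48 each. RPSA stood at -0.47, RACK1 and TFIIIA at -0.46 and cytochrome c at -0.44. Of 15859 fragments 1447 were at least 2-fold higher and 298 at least 2-fold lower, and of 84 families 4 and 0. The fragment counts depend on the settings: 108 were lower with TMM scaling, 31 with a pseudocount of 5, and 5935 were higher and 2170 lower with at least 30 counts summed. The median of all fragments was -0.28, and TMM scaling, which subtracts -0.11 from each ratio, changed none of these signs. Ratios were scaled to placed sequences, 3706059 of 8610325 in the Xiwi RIP and 4976954 of 8256085 in the RNA-seq. Scaled to all sequences, each ratio would be lower, and the counts past 2-fold were not computed on that scale. The Tc1/mariner transposase, which takes no place among the named families, was at 2.40 (2.32 to 2.48). The histone list (median 1.70) ranked above 99.6% of random lists of like abundance, and 5S rRNA, which has no poly(A) tail, was higher as well (5.10, 4.42 to 5.87), as a residue of the rRNA removal stated for these files. The ribosomal protein list (median -0.27) ranked above 55.9%.

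In the Xili RIP the mitochondrial families and histone H4, H2B and H2A were at least 2-fold higher. Histone H3 did not reach 2-fold except with TMM scaling. COX1, cytochrome b and COX3 had log2 ratios over RNA-seq of 4.94, 4.85 and 4.78, and H4, H2B, H2A and H3 of 2.49, 1.74, 1.72 and 0.97. UBE2D and beta-catenin were at 0.82 each and PIWIL1 at 0.45. TFIIIA was the lowest family at -0.74 (-0.97 to -0.54), followed by DDX4 at -0.55, RPS12 at -0.48, HSC70 at -0.46, VCP at -0.44, protein phosphatase 2A at -0.42, ubiquitin and ATP synthase beta at -0.41 and elongation factor 1 alpha at -0.40. Of 17112 fragments 1474 were at least 2-fold higher and 159 at least 2-fold lower, and of 86 families 6 and 0. The lower fragments numbered 81 with TMM scaling and 15 with a pseudocount of 5, and with at least 30 counts summed 6414 were higher and 1411 lower. Placed sequences were 4293704 of 8131782 in the Xili RIP and 4976954 of 8256085 in the RNA-seq. Scaled to all sequences, each ratio would be lower here too, and the counts past 2-fold were not computed on that scale. The histone list (median 1.73) ranked above 99.9% of random lists, and the Tc1/mariner transposase was at 1.07. Across 15400 fragments, which are not independent replicates, the RIP ratios of Xiwi and Xili had a Pearson correlation of 0.910 and a Spearman correlation of 0.819. Unchanged libraries drawn from a common profile, which share counting error alone, gave 0.467 and 0.439 in 20 simulations. The observed covariance of 0.514 exceeded the simulated 0.0180. A bias of the shared RNA-seq library, such as poly(A) selection, would enter both RIP ratios and was not simulated. The excess therefore does not show that Xiwi and Xili hold common transcripts.

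**Figure D2:**
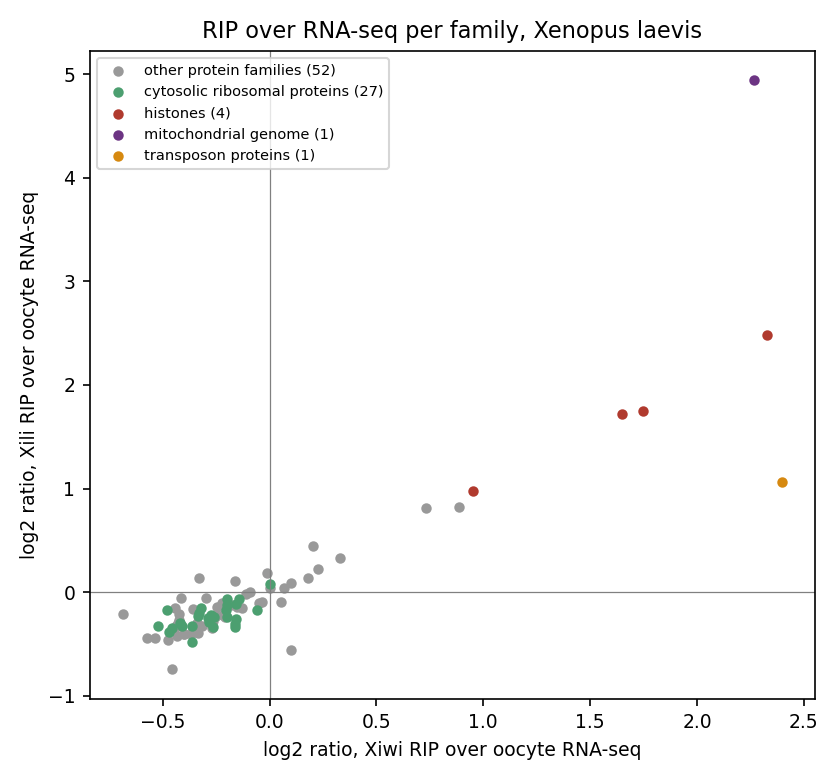
Log2 ratio of distinct sequences over the oocyte RNA-seq per family, Xiwi RIP on the horizontal and Xili RIP on the vertical axis (1 library each; colours mark the histones, ribosomal proteins, mitochondrial genome and transposon proteins). Mitochondrial COX1 lies at 2.27 and 4.94, histone H4 at 2.33 and 2.49, and Vg1 at -0.69 on the horizontal axis.

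Set directly against each other, the Xiwi RIP and the Xili RIP differed most in mitochondrial transcripts. Cytochrome b (-3.24), COX3 (-2.79) and COX1 (-2.68) were at least 2-fold lower in the Xiwi RIP, and the Tc1/mariner transposase was at least 2-fold higher (1.33, 1.27 to 1.39). None of the other named families reached 2-fold. DDX4 (0.65, 0.48 to 0.84) and TFIIIA (0.29, 0.04 to 0.54) had the largest ratios toward the Xiwi RIP, and Vg1 (-0.48, -0.65 to -0.31), the ADP/ATP translocase (-0.46) and peroxiredoxin (-0.36) the next largest toward the Xili RIP. Histones lay near 0 (median -0.05, above 42.9% of random lists). RPS15A at 0.17, HMGB1 and RPL37A at 0.14, RPL35A and RPS12 at 0.12, RPS24 at 0.10, NME at 0.08 and RPL11 at 0.07 completed the higher side, and with the sense strand alone RPL35A (-0.0026) and RPS24 (-0.0039) lay below 0. RPL23 (-0.31), cytochrome c (-0.29), ribonucleotide reductase M2 (-0.27) and PIWIL1 (-0.25) completed the lower side. Of 14610 fragments 378 were at least 2-fold higher and 119 at least 2-fold lower in the Xiwi RIP, and of 86 families 0 and 3. With a pseudocount of 5, 63 were lower, and with at least 30 counts summed 1130 were higher and 679 lower. Ratios were scaled to placed sequences, 3706059 of 8610325 in the Xiwi RIP and 4293704 of 8131782 in the Xili RIP. Scaled to all sequences, each ratio would move toward the Xili RIP, and such values were not computed. These are comparisons of 1 library with 1, with no replicate check.

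Small RNAs from the Xiwi and Xili IPs of X. laevis oocytes were compared in length, base preference and pairing, the marks of piRNAs. Both sets peaked at 29 nt and most began with U: 62.0% of 18360851 sequences of 24 to 32 nt in the Xiwi IP and 64.7% of 21936521 in the Xili IP. Position 10 held A in 34.7% and 30.9%. A partner on the opposite strand with a 10-nt overlap of 5′ ends is the mark of the ping-pong cycle. It was sought at plus-strand 5′ end positions on fragments built from the small RNAs, and not for all sequences. These positions numbered 582556 in the Xiwi IP and 669482 in the Xili IP. Such a partner was found for 14.2% (14.1 to 14.3) of them in the Xiwi IP and 6.21% (6.15 to 6.27) in the Xili IP. The mean over the other overlaps was 10.0% and 4.86%, and the next highest, at 11 nt, was 13.5% and 6.03%. On fragments built from RNA-seq and RIP sequences the order of the IPs was the opposite, with 4.38% in the Xiwi and 11.5% in the Xili IP. The 10-nt share was 1.42 times the mean of the other overlaps in the Xiwi IP and 1.28 times in the Xili IP. Identical sequences numbered 2016405, 11% of the Xiwi and 9.19% of the Xili set, and sequences with the same first 20 nt made up 23.2% and 32.9%. Pair frequencies in distinct sequences depend on how densely a fragment is covered, so the percentages of the IPs are not on a common scale.

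**Figure D3:**
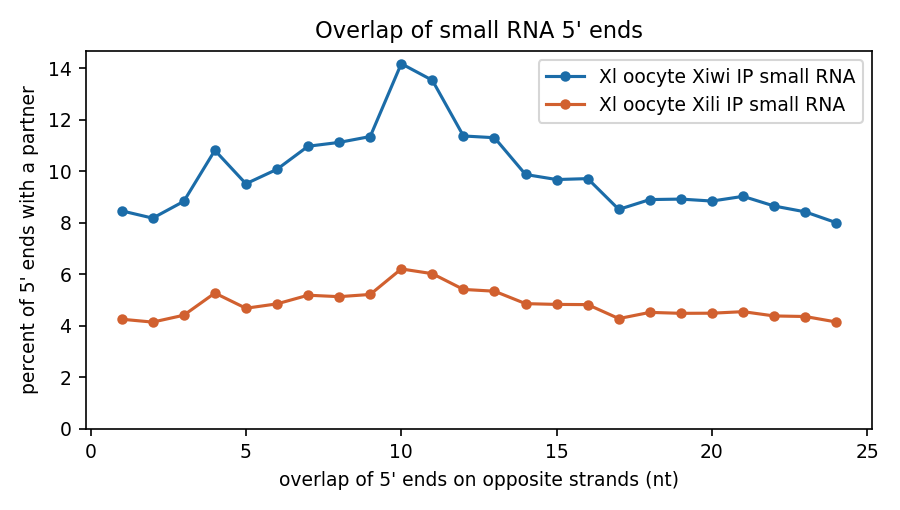
Percent of small RNA 5′ end positions on small-RNA-built fragments with a partner on the opposite strand, by overlap in nt (blue: Xiwi IP, orange: Xili IP, 1 library each). Both curves peak at 10 nt, at 14.2% and 6.21%.

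The strand of small RNAs matching transposon proteins differed between the IPs. Antisense sequences made up 54.5% (53.9 to 55.1) of those in the Xiwi IP and 89.0% (88.7 to 89.2) of those in the Xili IP. Tc1/mariner transposase had 66.2% and 98.5% antisense, gypsy reverse transcriptase 53.3% and 93.5%, and L1 reverse transcriptase 52.9% and 78.9%. Other protein families were almost all sense, with 0.228% and 0.162% antisense. Per strand, the log2 ratio of the Xiwi over the Xili IP was 3.66 for sense and -1.28 for antisense Tc1, 2.21 and -1.43 for gypsy and 0.72 and -1.02 for L1. These ratios are scaled to the sequences placed on small-RNA-built fragments, 4599656 in the Xiwi and 7546178 in the Xili IP. Sense L1 had 4681 and 4675 sequences, so its 0.72 comes almost wholly from the scaling. On fragments built from RNA-seq and RIP sequences, Tc1 gave 1.92 for sense and -2.43 for antisense, scaled to the 325277 and 309320 sequences placed there. Among sense small RNAs of messenger families CDK1 (3.69), RPS3 (3.21), Vg1 (3.16), HSC70 (2.68) and ribonucleotide reductase M2 (2.67) had the largest ratios toward the Xiwi IP, and histone H4 had the lowest ratio (-0.78, -1.17 to -0.41). Over 26907 fragments built from the small RNAs, 3246 were at least 4-fold higher in the Xiwi and 128 in the Xili IP, with a Spearman correlation of 0.305 across fragments, which are not independent replicates. The 4-fold counts depend on the scaling to placed sequences, and counts scaled to all sequences of each IP were not computed. On fragments built from RNA-seq and RIP sequences the counts were 138 and 60 of 678. The median log2 ratio over all fragments lay toward the Xili IP, at -0.38 and -1.09 in the same order. Of 7555 unnamed fragments with enough sequences in both, 44.5% had their majority on opposite strands, 1299 of them with over 80% on opposite strands. The strand shares of the IPs correlated positively across these fragments (Spearman 0.544), so the strands leaned toward agreement. The larger strand held a median of 82.9% in the Xiwi and 99.1% in the Xili IP.

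**Figure D4:**
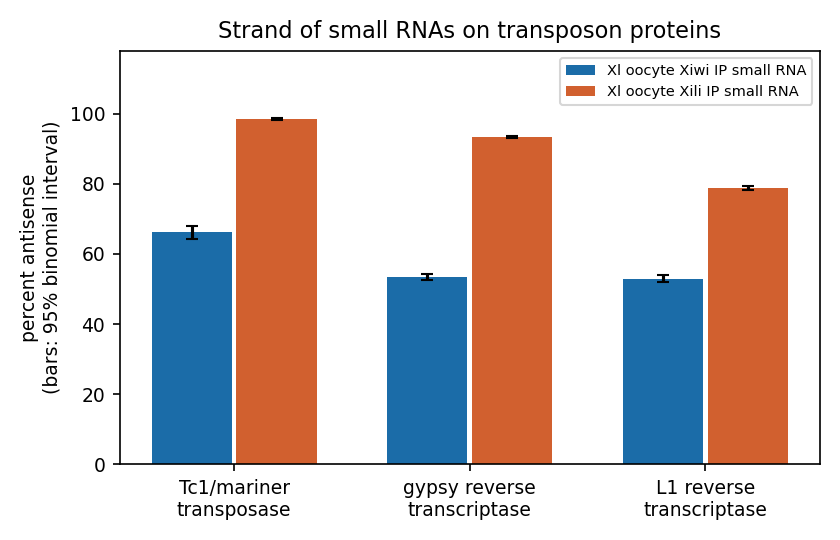
Percent of small RNAs on each transposon protein that are antisense (bars from 0; blue: Xiwi IP, orange: Xili IP; error bars: 95% binomial interval). Tc1/mariner has 66.2% in the Xiwi and 98.5% in the Xili IP, gypsy 53.3% and 93.5%, and L1 52.9% and 78.9%.

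Whether transcripts with more small RNAs were more enriched in the RIP was tested across fragments, which are not independent replicates. The Spearman correlation between small RNA density on both strands and the RIP ratio of the same protein was 0.0992 for Xiwi over 15859 fragments and 0.165 for Xili over 17112. Among fragments of over 100 small RNAs per kb the median RIP ratio was 0.52 for Xiwi (342 fragments) and 2.25 for Xili (108 fragments), against -0.32 and -0.27 for fragments without small RNAs. Over all fragments with small RNAs it was -0.27 for Xiwi and -0.18 for Xili. With at least 1000 counts summed, the correlations were 0.195 and 0.246, and the medians over 100 small RNAs per kb were 1.17 for Xiwi (42 fragments) and 1.74 for Xili (13 fragments). The Xili median of 1.74 is the ratio of histone H2B, so the dense fragments include a histone. Small RNAs on histone families were almost all sense (0.274% antisense over both IPs). A high density therefore need not reflect complementary small RNAs.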

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

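All tests below except the share of transposon-protein fragments more antisense in the Xili IP were chosen only after the result was seen.

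Signals outside the comparisons were present in the CLIP libraries. Reads matching 20 microRNA sequences written down from general knowledge numbered 66 in ovary Xili CLIP, 198 in ovary Xiwi CLIP A, 75 in ovary Xiwi CLIP B and 329 in testis Xiwi CLIP. The RNA-seq reads are 51 nt long, longer than a microRNA, so they give no control. Unnamed fragments of high copy number, which no protein or anchor sequence identified, took 1.40% of reads in ovary Xili CLIP, 3.50% and 2.64% in ovary Xiwi CLIP A and B and 3.14% in testis Xiwi CLIP. They were chosen for their high counts in CLIP, so their level in RNA-seq is no control either. What raised both is that reads not used by any comparison exceeded the limit of 3 counts that a count of 0 allows. No explanation was tested for either.

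Histone families were higher in both RIPs than in the X. laevis RNA-seq, at least 2-fold for 3 of 4 in each. With TMM scaling the remaining family, H3, passed 2-fold in both RIPs as well. Small RNAs complementary to histone transcripts within 1 mismatch are argued against: 0.274% (4 of 1461) of the small RNAs on histone families were antisense. Pairing with more mismatches and sequences matching several features were not counted, so complementary small RNAs of those kinds stay open. Poly(A) selection of the RNA-seq library stays open as a technical explanation, since 5S rRNA, without a poly(A) tail, was also higher in the Xiwi RIP, with a log2 ratio of 5.10 (4.42 to 5.87, counts 459 and 18), and so was U2 snRNA, at 5.84 (4.78 to 7.17). The 5S sequences are a residue, since rRNA was removed from these files. Histone enrichment may therefore reflect the RNA-seq library and not binding by Xiwi or Xili, and binding itself was not tested.

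Mitochondrial transcripts were higher in the Xili RIP than in the Xiwi RIP. Less poly(A) selection in the Xili RIP is argued against by 5S rRNA, which was higher in the Xiwi RIP, with a log2 ratio of 0.54 (0.34 to 0.74), and U2 snRNA, which is no rRNA, was higher there too (0.94, 0.67 to 1.22). The 5S counts are a residue of the rRNA removal and filled 64.3% and 61.7% of the possible positions in the Xiwi and Xili RIP, which draws the ratio toward 0. Complementary small RNAs within 1 mismatch are argued against as well, with 0% antisense (0 of 84, up to 4.30%) on mitochondrial transcripts in the Xili IP. Pairing with more mismatches and sequences matching several features were not counted and stay open. More mitochondria in the Xili RIP material could explain it: of 5 mitochondrial transcripts, 12S rRNA lay nearest to 0, at -1.85 (-1.94 to -1.75), with 93.7% of its positions filled in the Xili RIP. An association of Xili with mitochondria would predict the same and was not tested.

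Small RNAs of transposon proteins were more antisense in the Xili IP than in the Xiwi IP. A few fragments do not decide it, since 87.0% (114 of 131) of the fragments were more antisense in the Xili IP. Mismatched matches from related copies are argued against, because with perfect matches alone the share was 88.0% and 56.2%, a difference of 31.9 percentage points. Breakdown products of sense transcripts in the Xiwi IP and a difference in purity between the IPs were not tested and stay open. A sense excess in the Xiwi IP was not confined to transposon proteins. On fragments built from RNA-seq and RIP sequences, most messenger families measured had sense log2 ratios (Xiwi over Xili IP) above 0, up to 3.69 for CDK1. Histone H4 (-0.78) and H2A (-0.31) lay below 0, and sense Tc1 was at 1.92 there. A biological candidate explanation is that sense Xiwi sequences are made opposite antisense Xili sequences: 48.9% (45.9 to 51.9) of the 1082 sense Tc1 sequences of the Xiwi IP had A at position 10, against a mean of 30.4% at the other positions from 2 to 24. Position 4, at 45.4%, came close, so base composition may account for part of it. Of 271 sense Tc1 sequences of the Xili IP, 40.2% had A at position 10, 42.4% at position 11 and 45.4% at position 4. No Xili sequence enters the Xiwi measure, so it cannot tell pairing with Xili sequences from pairing among Xiwi sequences. That sense Xiwi sequences are made opposite antisense Xili sequences stays a hypothesis found and tested on the same data, from 1 library per IP.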

How the results depend on the processing

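Tests with the X. laevis sense strand alone were chosen only after the result was seen; the other alternatives were planned. Of 977 alternative values of named families, 816 kept direction and side of the threshold or moved within error, 104 kept direction and no longer passed, 1 newly passed, 49 moved and 7 reversed. Values without an ovary Xiwi replicate have no p, so for them direction alone was checked. For families named as not passed, keeping the side means that they again did not pass. For every change below the cause was not tested.

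For testis against ovary Xiwi CLIP (250 higher, 780 lower), the lower features numbered 421 with DESeq2 size factors and 394 with no low-count filter. Counts higher and lower were 18 and 1 with the DESeq2 test, 60 and 14 with each distinct sequence counted once, and 142 and 361 with perfect matches only. The 10 families named as lower kept their direction in each. Leaving out ovary replicate A or B moved the median of all features from -1.37 to -0.70 and -0.81.

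For ovary Xili against ovary Xiwi CLIP (17 higher, 2 lower), the counts were 3 and 0 with DESeq2 size factors, 2 and 0 with the DESeq2 test, 0 and 0 with distinct sequences (52 and 36 at an unadjusted p under 0.05 in edgeR) and 3 and 0 with perfect matches only. The lower count was 5 with no low-count filter and 1 with reads matching several features shared equally. Without replicate B, ARF1 reversed to -0.014 and stathmin to -0.22, while without replicate A they were at 1.00 and 1.02.

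For ovary Xiwi CLIP against poly(A) RNA (2149 higher, 3092 lower), 8596 were lower with no low-count filter, where calmodulin reversed to -0.17. The counts were 653 and 267 with the DESeq2 test and 857 and 980 with distinct sequences, and 1298 were higher with both stages as 1 group. Of 17 named families, 17 kept their call with DESeq2 size factors, perfect matches or shared reads, 16 with distinct sequences, 15 with both stages as 1 group, 12 with no filter and 4 with DESeq2. The median of all features (-0.74) was -0.40 with the DESeq2 test, -0.33 with distinct sequences and -1.59 and -0.96 without replicate A and B.

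For ovary Xili CLIP against poly(A) RNA (1466 higher, 2306 lower), 327 were higher with no low-count filter, where H3 reversed to -0.61 and H2A to -0.62. The counts were 139 and 6 with the DESeq2 test, 0 and 0 with distinct sequences (962 and 1216 at an unadjusted p under 0.05 in edgeR) and 813 and 1358 with both stages as 1 group. Of 15 named families, 13 kept their call with DESeq2 size factors or perfect matches, 15 with shared reads, 12 with both stages as 1 group, 11 with no filter and 0 with DESeq2 or distinct sequences.

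For stage 5-6 against 3-4, features at least 2-fold higher and lower were 4217 and 4261 with a pseudocount of 5, and 2049 and 3141 with distinct sequences, with 7 and 5 families. For the Xiwi RIP against RNA-seq, 31 were lower with a pseudocount of 5 and 108 with TMM scaling. The counts were 5935 and 2170 with at least 30 counts summed and 636 and 142 with the sense strand only. For the Xili RIP against RNA-seq, 15 were lower with a pseudocount of 5 and 81 with TMM scaling, with 6414 and 1411 at 30 counts and 600 and 84 on the sense strand. For the Xiwi against the Xili RIP, 63 were lower with a pseudocount of 5, with 1130 and 679 at 30 counts and 186 and 55 on the sense strand, where RPL35A reversed to -0.0026 and RPS24 to -0.0039.

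With small RNAs of at least 18 nt, 5′ U was 61.6% in the Xiwi and 64.2% in the Xili IP, A at position 10 was 34.1% and 30.7%, and a 10-nt partner 14.4% and 6.32%. Sequences with the same first 20 nt made up 23.2% and 32.9%. At 1000 counts summed, the density correlations were 0.195 for Xiwi and 0.246 for Xili. Counting distinct sequences, cytosolic rRNA was 4.07% in ovary Xili CLIP, 4.62% and 7.16% in ovary Xiwi CLIP A and B, 5.38% in testis CLIP and 0.695% and 1.71% in the RNA-seq of stages 3-4 and 5-6, and the replicate correlations were 0.484 (Pearson) and 0.475 (Spearman) across fragments.

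Alternatives that need read numbers in X. laevis were not run: weighting by reads, minimum reads per shared sequence and leaving out the 100 most abundant sequences. Regions of transcripts were not run for lack of coding annotation. The smallest CLIP library has 613343 reads, with 1.22% of them on named families. Whether depth or the spread between the Xiwi replicates limits the CLIP comparisons was not tested.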

Other observations

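No tests were run on the values below, which were chosen only after they were seen.

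In the X. laevis small RNA libraries, U2 snRNA sequences were 75.7% sense in the Xiwi IP and 25% sense in the Xili IP, 1 library each. Of 20 microRNAs looked for, 7 were found in ovary Xili CLIP, 13 and 12 in ovary Xiwi CLIP A and B and 12 in testis Xiwi CLIP.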
